A study of Mus musculus with 30 samples.

How the data were processed

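Cells of the mouse cochlea were profiled at the progenitor stage, as p27-GFP+ cells sorted from embryonic day 13 cochleae, and as Atoh1-GFP+ hair cells sorted at embryonic day 17 from cochleae labelled wild type or Pou4f3KO. The 30 samples form 15 groups with 2 samples each. They are 6 RNA-seq libraries from 3 groups and 24 peak lists from 12 groups. The peak lists cover ATAC-seq, which marks accessible chromatin, and CUT&RUN, which maps where a protein or a modified histone sits on DNA. Groups and replicate numbers came from the sample titles. For 2 samples, ATOH1 CUT&RUN replicate 2 and H3K4me1 CUT&RUN replicate 1 labelled Pou4f3KO, the title gave day 17 while the stage label gave day 13.5, and the title was followed. Nothing in the labels says that replicates come from separate animals, so p-values measure only the spread between these samples.

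The deposited RNA tables hold, per gene, expected counts estimated with RSEM, per the submitters' processing notes, and were not normalized. The TPM values that the authors deposited beside them entered no test. The effective length in the deposited RNA tables, in bp, is the gene length less the mean fragment length, per the file headers, and served to compare fragment lengths. Expected counts were rounded to whole numbers, since between 4.69% and 15.7% of all values in a library, zeros included, were not whole. Peak lists were called per library by the authors and deposited with a fold enrichment at the summit, a −log10 p, a −log10 q and a summit offset in bp from the peak start. The fold and the −log10 p and q are the authors' peak scores. They served only to rank or filter peaks within a list. The submitters' processing notes name STAR, RSEM, DESeq2, Bowtie2, MACS2 and UMI-tools and the mouse build mm10. Their roles, options and versions are not given in the sources used here. The lists did not all pass through the same steps. The score was capped at 1000, some peak numbers were missing and a region of very high signal on chromosome 2 was absent in both ATAC lists of progenitors and of wild-type hair cells, in POU4F3 replicate 2, and in ATOH1 and H3K4me1 replicate 2 labelled Pou4f3KO. The other lists, with both ATAC lists labelled Pou4f3KO among them, showed none of these, so in ATAC-seq of hair cells this difference ran with the label.

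Of 48709 gene identifiers, 48349 matched a symbol. Genes were tested with edgeR 4.0.16 (TMM scaling, the default filter on low counts, quasi-likelihood test, Benjamini-Hochberg adjusted p at 0.05) in R 4.3.3, in each comparison with only the 4 libraries compared. Log2 fold changes are given with a standard error (SE) from the same fit. Levels are CPM, computed by scaling the deposited expected counts to the library total. Where one group was at 0 in both libraries, the fold is a lower bound against a floor of 3 counts over the group. Floors and intervals cover counting error only. The counting is not stated to use strand, so overlapping and antisense genes were not separated, and members of multicopy families such as the U1 and 7SL RNA genes and the globins share reads with near-identical copies and are uncertain.

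The 18 gene lists were fixed before the data were examined, as were the design, the alternatives and the rule for named genes. That rule took Pou4f3 and Atoh1 in every library. It took the 10 genes with the largest log2 fold change in each direction among those that passed the test, whose replicates did not overlap and whose mean was at least 5 CPM, leaving out numbered Gm and Rik symbols. From each list it took up to 4 members with the smallest p that passed, or the most abundant pair if none passed. Some genes that the rule takes are not reported here. For chromatin it took the strongest ATOH1 site linked to each of 11 genes and the 5 strongest POU4F3-dependent sites. Lists of at least 5 tested genes were tested with camera of limma 3.58.1 against the other genes, with a preset correlation of 0.01 and again with an estimated correlation. The test with an estimated correlation rests on the spread of only 4 libraries and has little power. A list that did not pass there is therefore not shown to be unchanged, nor its members to be correlated.

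Peak intervals were compared with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 under Python 3.11.15. Peaks on chromosomes 1 to 19, X and Y were used. A reproducible region was a union of overlapping peaks that held a peak of both replicates, and a minimum overlap of 1 bp counted as shared. A site was called accessible or bound where it overlapped a reproducible region of the assay concerned. It was called lost where it overlapped no ATOH1 peak in either list labelled Pou4f3KO, and POU4F3-dependent where it was also POU4F3-bound. Accessibility was called lost where a site accessible in wild type overlapped no reproducible ATAC region labelled Pou4f3KO. A peak in a single ATAC list labelled Pou4f3KO therefore still counted as loss, a looser rule than for ATOH1. Shares carry Wilson 95% intervals. Background shares came from the same sites placed at random 20 times between 100 kb and 5 Mb away. Odds ratios across sites were computed with Fisher's exact test and, over 5 strata of peak score, by the Mantel-Haenszel method of statsmodels 0.14.6. Sites are not independent replicates, so these intervals describe the lists at hand.

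Without a genome sequence, the planned motif search was not run. The gene table, of the assembly GRCm38.p6 that mm10 names, was used here without strand. Distal therefore means that the site's strongest summit lay over 2 kb from either end of any gene. A site was linked to every protein-coding gene its summit lay inside, or else to the nearest within 100 kb, and distances to genes run from that summit. Shares of gene lists near sites were therefore tested among protein-coding genes, a background chosen after the data were seen.

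The steps were tested on simulated data. In 15515 simulated genes modelled on the hair cell libraries labelled Pou4f3KO and wild type, edgeR found 5 of 67 genes changed 2-fold, 33 of 67 changed 4-fold and 47 of 66 changed 8-fold, and 4 of its 89 calls were unchanged genes. In 17678 simulated genes modelled on wild-type hair cells and progenitors, it found 14 of 67 at 2-fold, 34 of 67 at 4-fold and 49 of 66 at 8-fold, and 1 of its 98 calls was unchanged. Far fewer genes changed in these simulations than edgeR called in the real comparisons. Both groups were also given the same spread, so these rates may not carry over. Over 40000 simulated sites made with an odds ratio of 2, the stratified method returned 1.97.

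The alternatives fixed in advance were DESeq2 1.42.0 and its size factors, limma-voom, no filter on low counts, all 6 libraries in one fit, a replicate block, protein-coding genes only, peaks with a −log10 q of at least 5, the 20000 strongest peaks of every list, 50% of a site covered, a 200 bp window around the summit, distal sites only, a link of 50 kb, and each replicate left out in turn. Offsets for effective length, protein-coding genes over 1 kb only, and sites with a peak in either replicate list were added after the data were seen. Leaving out a library leaves its group with a lone sample, which is then assumed to vary like the other group. Figures were drawn with matplotlib 3.10.9.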

Results

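RNA was measured in p27-GFP+ progenitors sorted from mouse cochleae at embryonic day 13 (E13) and in Atoh1-GFP+ hair cells sorted at embryonic day 17 (E17), with 2 libraries per group. Hair cells are the mechanosensory cells of the cochlea, and ATOH1 and POU4F3 are transcription factors needed for them to form and to survive. Total expected counts were 17057751 and 19570946 in progenitors, 12833779 and 15213181 in wild-type hair cells, and 3966727 and 3581930 in the hair cell libraries labelled Pou4f3KO. ATAC-seq covered all 3 kinds of cell. CUT&RUN covered ATOH1, H3K4me1 and H3K27ac in hair cells of both labels, and POU4F3, H3K4me3 and H3K27me3 in wild-type hair cells, with 2 peak lists per group holding between 41755 and 236778 peaks. The question was which sites ATOH1 occupies in hair cells, whether they were already accessible in progenitors, and how far ATOH1 and its target genes depend on POU4F3.

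The RNA libraries differed in makeup along with their group. Protein-coding genes took 91.7% and 93.5% of counts in progenitors, 74.9% and 72.9% in wild-type hair cells, and 81.7% and 90.2% in the libraries labelled Pou4f3KO. Mitochondrial genes took 2.21% and 1.49%, 9.82% and 12.6%, and 11.0% and 4.25% in the same order. The effective lengths corresponded to mean fragments of 190.2 and 189.3 bp, 75.2 and 75.1 bp, and 181.2 and 217.9 bp. Progenitor libraries were made from polyadenylated RNA and hair cell libraries from total RNA with another kit. Replicates correlated across genes with a Pearson r of 0.963 in progenitors, 0.977 in wild type and 0.866 in the libraries labelled Pou4f3KO. Every pair differed by more than sampling noise, with a chi-square per degree of freedom between 18.7 and 50.8.

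Pou4f3 (ENSMUSG00000024497.3), on mm10 chromosome 18 from 42394597 to 42396093, was not lower in the hair cell libraries labelled Pou4f3KO. Its level was 962.5 and 1587 CPM there against 595.6 and 544.6 CPM in wild-type hair cells and 0.469 and 1.64 CPM in progenitors. The log2 fold change between the hair cell groups was 0.83 (SE 0.28, edgeR adjusted p = 0.0650, 2 libraries per group), and the adjusted p ranged from 1.47e-17 to 0.403 over the alternatives, all with a positive fold. Without replicate 1 or replicate 2 labelled Pou4f3KO the log2 fold change was 1.16 or 0.50 and the difference passed, as it did in DESeq2, in limma-voom, without the filter on low counts, among protein-coding genes alone and with effective length taken into account. Atoh1, on chromosome 6 from 64729125 to 64731245, stood at 362.5 and 665.0 CPM in the libraries labelled Pou4f3KO, 364.0 and 329.9 CPM in wild-type hair cells and 2.93 and 6.08 CPM in progenitors. Its log2 fold change between the hair cell groups was 0.24 (SE 0.30, edgeR adjusted p = 0.567), and it was −0.19 without replicate 2 and 0.62 without replicate 1 labelled Pou4f3KO, the latter past the threshold. The labels' protocol for the wild-type hair cell RNA words the cochleae as wild type and mutant at once, so the genotype behind those values is not certain. The allele is not described in the labels, so the RNA level neither checks nor excludes a mutation that leaves a transcript, and the groups below are named by their labels only.

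**Figure D1:**
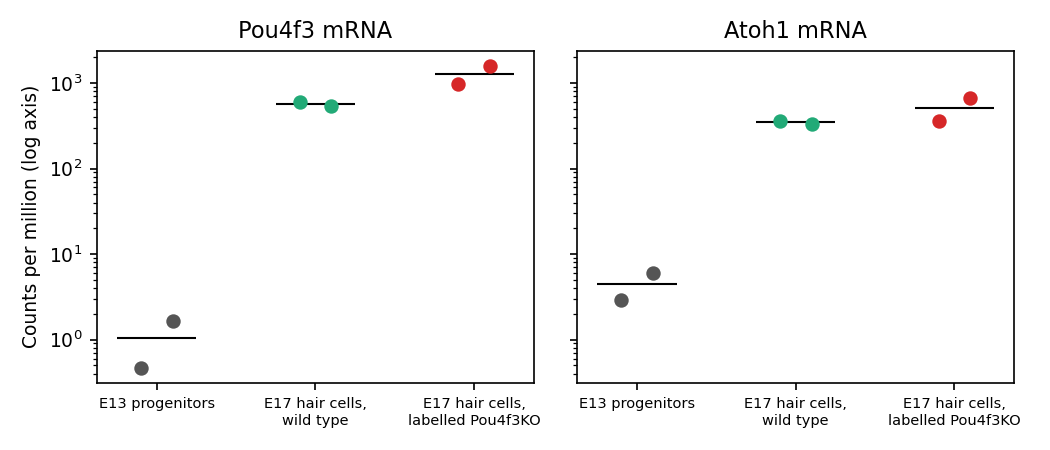
CPM of Pou4f3 and Atoh1 in each RNA library on a log axis, with 1 point per library and a line at the mean of the 2 libraries per group. Pou4f3 stood at 962.5 and 1587 CPM in the libraries labelled Pou4f3KO and at 595.6 and 544.6 CPM in wild-type hair cells.

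Most measured genes of hair cell identity, mechanotransduction and synapse were higher in wild-type E17 hair cells than in E13 progenitors. The lists of hair cell transcription factors, hair bundle and synapse genes were called up by limma's camera at the preset correlation but not with an estimated correlation (adjusted p = 0.206 each). Pou4f3 rose by a log2 fold change of 9.61 (SE 0.46, edgeR adjusted p = 1.25e-06, 2 libraries per group) and Atoh1 by 6.83 (SE 0.37, adjusted p = 1.91e-06). Of 32 measured hair cell transcription factors, 24 rose and 6 fell, and their list summed to 6753 and 6247 CPM in wild-type hair cells against 7073 and 6953 CPM in progenitors. Among those that rose were Lhx3, a LIM-homeodomain factor, at least 1897-fold, Gfi1, a zinc finger repressor, by 10.60 (SE 0.50), and Insm1, a zinc finger factor that sets outer hair cell identity, by 10.36 (SE 0.50). Of 49 genes of the hair bundle, the stereocilia that sense sound, 39 rose and 6 fell. Those that rose included Myo15, a stereocilia tip myosin, at 13.44 (SE 0.43), Ptprq, a shaft-connector phosphatase, at 13.35 (SE 0.39, edgeR adjusted p = 5.5e-07), Loxhd1 at 12.35 (SE 0.36) and Myo3a, at least 4989-fold. Of 36 genes of synapse and excitability 29 rose. They included the active zone gene Rims2 at 9.21 (SE 0.32), Tmem255b at 13.12 (SE 0.45), the calcium buffer gene Pvalb, at least 1475-fold, and Chrna10, a subunit of the efferent acetylcholine receptor, at least 1270-fold. The 1 member that fell was Ptprd, chosen after its value was seen. The sodium channel gene Scn11a was at least 4379-fold higher.

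Progenitor and cell cycle genes were lower. In limma's camera these calls did not hold with an estimated correlation, at adjusted p = 0.384 for progenitor and adjusted p = 0.281 for cell cycle genes. Of 46 progenitor and supporting cell genes 29 fell and 9 rose. Fgf20, a growth factor of the prosensory domain, fell by 7.27 on the log2 scale (SE 0.38), as did the glutamate transporter gene Slc1a3, at −4.89 (SE 0.24), and the chromatin gene Hmga2, at −4.61 (SE 0.24), while Prox1 rose by 3.97 (SE 0.21, all edgeR adjusted p at or under 1.91e-06). Of 51 cell cycle genes 38 fell, among them Ccnd1, cyclin D1, at −4.38 (SE 0.21), the centromere gene Cenpa at −4.32 (SE 0.41), the condensin gene Ncaph at −2.89 (SE 0.28) and Hells at −2.47 (SE 0.25). The 3 that rose, Cenpe, Dnmt1 and E2f2, were chosen after their values were seen. The most strongly lower genes were Slc36a2, at least 643-fold, Gdpd2, at least 324.7-fold, the activin inhibitor gene Fst at −11.88 (SE 0.44), the tachykinin gene Tac1 at −11.68 (SE 0.45), the T-box gene Tbx1, at least 194-fold, the endothelin gene Edn1, at least 183-fold, the pseudogene Rps2-ps13 at −10.68 (SE 0.47), Slc26a4, which encodes the anion exchanger pendrin, at least 130-fold, the potassium channel gene Kcnj8, at least 128-fold, and Slc9a4, at least 116.9-fold. Of 14 members of the Notch list, which holds ligands and other genes, 11 were higher (limma's camera adjusted p = 0.246 with an estimated correlation). Dll1 was at least 1998-fold, Dll3 at least 1479-fold and Dll4 at least 472.9-fold higher, and Jag2 rose by 6.18 (SE 0.27). The 3 lower members were Jag1, Numb and Rfng, chosen after their values were seen. Jag1 encodes a Notch ligand of the prosensory domain and Rfng a glycosyltransferase that modifies Notch.

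Stress, apoptosis and early response genes moved both ways. Of 30 p53 targets and apoptosis genes 7 rose and 13 fell, with Phlda3 at −6.08 (SE 0.52), Bax at −2.21 (SE 0.20), Hrk at 7.33 (SE 0.74) and Btg2 at 2.05 (SE 0.23). Of 26 genes of the unfolded protein and integrated stress responses 8 rose and 8 fell. The factor gene Xbp1 fell by 2.84 (SE 0.21) and the chaperone gene Hspa5 by 2.00 (SE 0.23), while the serine synthesis gene Psat1 rose by 4.14 (SE 0.37) and Atf5 by 3.87 (SE 0.55). Of 32 immediate early genes, which also respond to tissue dissociation, 7 rose and 12 fell, with Ccn1 at −3.61 (SE 0.23), Ier2 at −3.35 (SE 0.29), Btg1 at −3.11 (SE 0.25) and Jun at −2.92 (SE 0.21). Of 126 deafness genes 67 rose and 35 fell, and 56 of the list's members stand in other lists too.

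Markers of other cell types and of the library kind differed with the same groups. Mesenchyme markers split, 4 up and 5 down of 13, with Lum at −7.23 (SE 0.31), Dcn at −5.47 (SE 0.38), Col2a1 at −4.00 (SE 0.28) and Fbn1 at −3.25 (SE 0.28), and Col3a1, Pdgfra, Pou3f4 and Tbx18 higher, named after their values were seen. Of 12 neuron markers 8 rose and Stmn2 and Tubb3 fell; the neurofilament genes Nefm and Nefl rose by 9.47 (SE 0.75) and 8.41 (SE 0.50), Ina was at least 169-fold higher, and Elavl4 rose by 3.40 (SE 0.40). Of 8 glia markers 2 rose, S100b at 4.44 (SE 0.82) and Fabp7, and 4 fell, among them Erbb3 at −4.19 (SE 0.23), Sox10 at −2.37 (SE 0.19) and Mbp at −1.28 (SE 0.24). Of 5 erythroid markers 4 rose, the globin genes Hbb-bs at 7.52 (SE 1.30), Hba-a1 at 5.75 (SE 1.10), Hba-a2 at 5.41 (SE 1.36) and Hbb-bt, at least 26.5-fold. Of 4 immune markers Laptm5 rose by 7.90 (SE 0.58) and C1qb was at least 12.98-fold higher. Of 5 endothelial markers Flt1 rose by 6.13 (SE 1.20) and Pecam1 by 3.67 (SE 1.14), and Vwf was at least 14.2-fold lower. Of 4 melanocyte markers Kit rose by 2.24 (SE 0.35), and Pmel and Dct fell by 5.28 (SE 1.57) and 4.42 (SE 1.30). Of 29 genes that mark total RNA, such as small RNAs without a poly(A) tail and replication histones, 26 rose. They included Rn7s1, at least 96180-fold, Rpph1, at least 38290-fold, Rn7sk, at least 22870-fold, Rmrp, at least 14310-fold, and Hist1h1c at 6.62 (SE 0.31). Outside that list, Rn7s2 was at least 94740-fold, AY036118 at least 43900-fold and n-R5-8s1 at least 3977-fold higher.

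In all, edgeR called 5161 of 17678 tested genes higher and 4678 lower in wild-type hair cells than in progenitors. Adjusted over the list alone, the calls were 24 up and 6 down for transcription factors, 39 and 6 for the hair bundle, 30 and 1 for synapse, 67 and 36 for deafness, 9 and 29 for progenitor, 3 and 39 for cell cycle, 11 and 3 for Notch, 8 and 13 for p53, 8 and 8 for stress, 7 and 13 for immediate early and 27 and 0 for the total RNA list. They were 4 and 5 for mesenchyme, 8 and 2 for neuron, 2 and 4 for glia, 4 and 0 for erythroid, 2 and 0 for immune, 2 and 1 for endothelial and 1 and 2 for melanocyte. Against the other genes, limma's camera gave adjusted p-values of 0.000383 for transcription factors, 6.76e-09 for the hair bundle, 1.08e-09 for synapse, 0.00555 for deafness, 0.00318 for Notch, 2.88e-10 for the total RNA list and 0.0238 each for neuron and erythroid markers, all up, and of 0.000383 for progenitor and 1.66e-08 for cell cycle, both down. With an estimated correlation none passed in limma's camera: adjusted p = 0.206 for transcription factors, hair bundle, synapse and total RNA, adjusted p = 0.281 for deafness, cell cycle, neuron and erythroid, adjusted p = 0.246 for Notch and adjusted p = 0.384 for progenitor. The other lists did not pass at the preset correlation, with limma's adjusted p = 0.234 for p53 and immediate early genes, 0.302 for glia, 0.639 for endothelial, 0.685 for mesenchyme and 0.865 for stress, and immune and melanocyte lists were too short to test. Stage, sort marker, kit and RNA type all differed between the groups, so their shares cannot be separated. Without wild-type replicate 1 or 2 the calls fell to 3392 up and 2848 down or to 3420 and 2993, and calls of Hba-a1, Hba-a2, Pecam1, Vwf, Pmel and Dct ended without replicate 1 and of Hba-a2, C1qb and Vwf without replicate 2. Hba-a2 and Dct also ended without progenitor replicate 2, and Dct in DESeq2, limma-voom and the fit of all libraries, the last of which also ended Pecam1. By limma's camera the neuron list rose to an adjusted p = 0.0546 without wild-type replicate 1 and 0.0890 without replicate 2, and the erythroid list to 0.0546 without wild-type replicate 1 and 0.0669 and 0.0634 without progenitor replicates 1 and 2.

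Hair bundle genes were lower and cell cycle, progenitor and p53 genes higher in the hair cell libraries labelled Pou4f3KO than in wild type, a comparison in which Pou4f3 mRNA itself was not lower. The calls of these lists in limma's camera did not hold with an estimated correlation (adjusted p = 0.592 for hair bundle, cell cycle and progenitor, adjusted p = 0.510 for p53), a test of little power with 4 libraries. Of 49 hair bundle genes 19 fell and 6 rose. Adgrv1, an ankle-link receptor, fell by 2.89 on the log2 scale (SE 0.33) and Tmie, a part of the transduction channel complex, by 2.32 (SE 0.23, edgeR adjusted p = 0.00343), while Myh14 stood at −2.32 (SE 0.28) and at −0.39, not passing, once effective length was taken into account. Hair bundle genes together took 11398 and 14218 CPM against 19340 and 17856 CPM in wild type and 4916 and 5359 CPM in progenitors. Of 34 hair cell transcription factors 15 fell and 3 rose. Pax2, an otic paired-box factor, fell by 2.78 (SE 0.33) and Casz1 by 1.58 (SE 0.21), while Nhlh2 rose by 7.78 (SE 1.13), St18 by 7.25 (SE 1.02) and Ikzf2, named after its value was seen, was the remaining riser. Of 38 genes of synapse and excitability 8 fell and 5 rose. Rims2 fell by 1.96 (SE 0.21), Bsn, which encodes the active zone scaffold bassoon, by 1.75 (SE 0.21) and Tekt1, which encodes the ciliary microtubule protein tektin 1, by 1.54 (SE 0.21), while Snap91, a clathrin assembly gene, rose by 1.68 (SE 0.21). The others that rose, Calb1, Chrna9, Ocm and Rprm, were named after their values were seen. Of 121 deafness genes 31 fell and 15 rose. Gipc3 fell by 4.48 (SE 0.33), Myh9, a nonmuscle myosin heavy chain, by 3.13 (SE 0.22) and Bdp1 by 2.89 (SE 0.26), and Crym, a thyroid hormone-binding crystallin, rose by 3.74 (SE 0.25).

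Among 50 cell cycle genes 19 rose and 2 fell. Gins2, of the replicative helicase, rose by 4.02 (SE 0.57), Mcm7 by 2.13 (SE 0.27) and Ccnd1 by 1.73 (SE 0.25), and Dnmt1, the maintenance DNA methyltransferase, fell by 1.73 (SE 0.20), as did Cenpf, named after its value was seen. Cell cycle genes together took 1029 and 1397 CPM against 629 and 604 CPM in wild type and 2063 and 2367 CPM in progenitors. Of 44 progenitor and supporting cell genes 12 rose and 3 fell. Slc1a3 rose by 2.94 (SE 0.25), Id1, an inhibitor of basic helix-loop-helix factors, by 2.47 (SE 0.23) and Fgf10 by 2.02 (SE 0.22), and Cdkn1b, which encodes the cyclin-dependent kinase inhibitor p27, fell by 2.85 (SE 0.32). Emx2 and Sox2, the others that fell, were named after their values were seen. Of 30 p53 targets and apoptosis genes 12 rose, among them the BH3-domain genes Bid at 3.13 (SE 0.52) and Bmf at 2.16 (SE 0.38) and Sesn2 at 3.02 (SE 0.48), and the 1 that fell, Dcxr, encodes a xylulose reductase and was named after its value was seen. Bmf did not pass with effective length taken into account, at 0.78.

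Of 26 stress genes 10 fell and 5 rose. Those that fell included the endoplasmic reticulum chaperone genes Pdia4 at −2.22 (SE 0.22), Hsp90b1 at −1.85 (SE 0.27), Calr at −1.62 (SE 0.22) and Hyou1 at −1.42 (SE 0.20). Those that rose, named after their values were seen, were Ddit4, Psat1, Sesn2, Shmt2 and Vldlr. Of 14 Notch genes Dner rose by 1.60 (SE 0.20) and Neurl1a by 1.56 (SE 0.33), and Mib1 fell by 1.63 (SE 0.23), Dll3 by 1.57 (SE 0.39) and Dll4, named after its value was seen, as well. Of 30 immediate early genes 4 rose, Myc at 3.20 (SE 0.36), Fosl2 at 2.66 (SE 0.57), Btg1 at 1.22 (SE 0.26) and Btg2, and 2 fell, Egr3 at −3.89 (SE 0.76) and Fosb. The largest increases were in Pdyn, which encodes the opioid precursor prodynorphin, at least 463-fold, Lhx2, a LIM-homeodomain factor, at 10.51 (SE 1.06), Pagr1a, at least 117-fold, Neurod1, a neuronal differentiation factor, at 9.03 (SE 1.30), Fhl1 at 8.52 (SE 0.93), the adhesion gene Clmp at 7.42 (SE 0.45), Slc35d3 at 7.33 (SE 0.67) and Phactr1 at 6.80 (SE 1.24).

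Markers of other cell types and of library kind differed with the label as well. All 4 of 14 mesenchyme markers that changed rose, Dcn at 5.73 (SE 0.55), Col1a2 at 4.99 (SE 1.47), Lum at 4.81 (SE 1.17) and Tbx18 at 4.03 (SE 1.03), and the list summed to 423 and 2284 CPM against 328 and 369 CPM in wild type. Of 13 neuron markers Neurod1, Pou4f1 at 4.20 (SE 0.54), Stmn2 and Tubb3 rose, and the neurofilament genes Nefm and Nefl fell by 4.56 (SE 0.23) and 3.31 (SE 0.45). Of 7 glia markers 4 rose, among them Erbb3 at 2.63 (SE 0.24), Mbp at 1.16 (SE 0.29) and S100b, and Sox10 fell by 1.89 (SE 0.29). Hbb-bt fell by 4.19 (SE 1.11) among 3 erythroid markers and Laptm5 rose by 2.51 (SE 0.42) among 4 immune markers. None of 5 endothelial markers and 2 melanocyte markers passed in edgeR. Kdr stood at 2.59 (SE 1.59) and Cdh5 at 2.48 (SE 1.49), negative without replicate 2 labelled Pou4f3KO at −2.52 and −2.46, Kit at −1.43 (SE 0.51) and Mitf at 0.95 (SE 0.55). Of 28 genes that mark total RNA 24 fell and none rose. Among them Rpph1 fell by 14.67 (SE 0.60), as did Hist1h1d at −5.04 (SE 0.31) and Hist1h1e at −4.94 (SE 0.27). The list also holds the nuclear long RNA Malat1, which fell by 4.55 (SE 0.32). Malat1 stood at 12206 and 5504 CPM in the progenitor libraries of polyadenylated RNA and at 6805 and 6578 CPM in wild-type hair cells. It therefore does not mark total RNA here. Outside that list, AY036118 was at least 9047-fold lower, Rnu2-10 at least 1416-fold, n-R5-8s1 at least 819.5-fold, Rnu1a1 at least 674.7-fold, Rny3 at least 446.7-fold, Snord17 at least 318-fold, Rnu3a at least 253.6-fold, and Rnu1b6 and Rnu1b2 at least 245-fold and 234-fold. The labels give the same kit and total RNA for both hair cell groups, yet these RNAs were scarce in the libraries labelled Pou4f3KO. Library makeup thus ran with the label. Its share in the gene, list and linked-gene differences between the hair cell groups cannot be separated from that of genotype.

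In all, edgeR called 2372 of 15515 tested genes higher and 2915 lower in the libraries labelled Pou4f3KO. Adjusted over the list alone, the calls were 6 up and 20 down for the hair bundle, 4 and 17 for transcription factors, 5 and 8 for synapse, 16 and 32 for deafness, 14 and 3 for progenitor, 20 and 2 for cell cycle, 14 and 1 for p53, 6 and 10 for stress, 2 and 3 for Notch, 3 and 1 for immediate early and 0 and 24 for the total RNA list. They were 3 and 0 for mesenchyme, 4 and 2 for neuron, 5 and 1 for glia, 0 and 1 for erythroid, 2 and 0 for immune, and 0 and 0 for endothelial and melanocyte. By limma's camera the hair bundle list was down at adjusted p = 0.00506 and the total RNA list at 5.46e-13, and the progenitor list was up at 0.00465, cell cycle at 6.68e-06 and p53 at 0.00506. With an estimated correlation none of these calls held in limma's camera: adjusted p = 0.592 for hair bundle, progenitor and cell cycle, and adjusted p = 0.510 for p53 and total RNA. The p53 list had an estimated correlation of −0.029, below the preset 0.01. Its unadjusted p in limma's camera still went from 0.00136 to 0.0680, so not passing there need not reflect correlated members. The other lists did not pass at the preset correlation in limma's camera, with adjusted p = 0.0893 for transcription factors, 0.106 for synapse, 0.363 for deafness and stress, 0.467 for Notch, 0.105 for mesenchyme, 0.122 for glia, 0.301 for neuron, 0.300 for immediate early and 0.881 for endothelial, and erythroid, immune and melanocyte lists were too short to test.

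**Figure D2:**
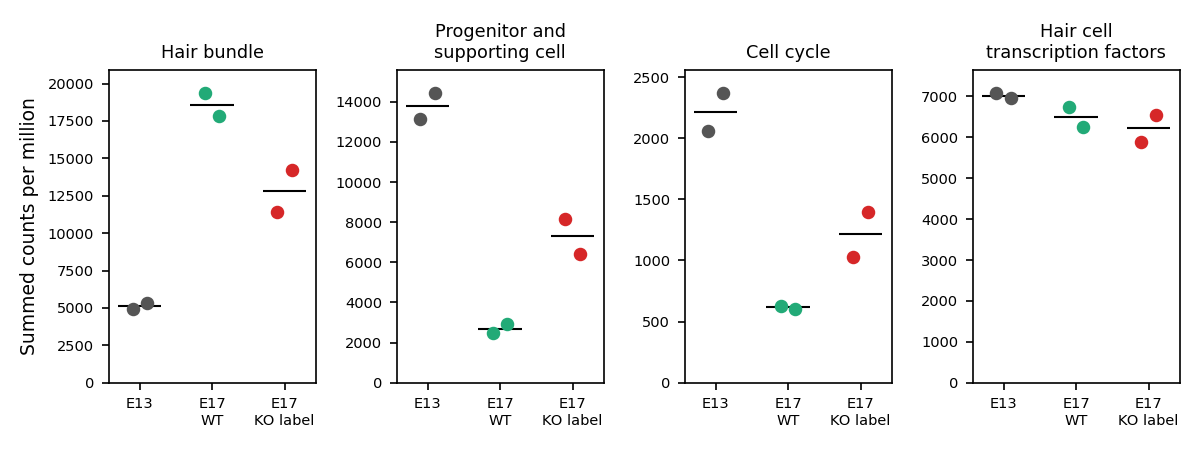
Summed CPM for hair bundle, progenitor and supporting cell, cell cycle and hair cell transcription factor genes in each RNA library, with 1 point per library and a line at the mean of the 2 libraries per group. Hair bundle genes took 11398 and 14218 CPM in the libraries labelled Pou4f3KO and 19340 and 17856 CPM in wild-type hair cells.

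The number of calls between the hair cell groups rested on which libraries entered. It was 3947 up and 4665 down without replicate 1 labelled Pou4f3KO, 4035 and 4702 without replicate 2, 213 and 610 without wild-type replicate 1, and 247 and 563 without wild-type replicate 2. Without wild-type replicate 1 or 2, edgeR no longer called, among others, Pagr1a, Casz1, Snap91, Tekt1, Fgf10, Dnmt1, Ccnd1, Dner, Mib1, Neurl1a, Dll3, Sesn2, Bmf, Calr, Hyou1, Hsp90b1, Egr3, Btg1, Fosl2, Lum, Tbx18, Col1a2, Sox10, Mbp and Laptm5. Bsn and Mcm7 were lost only without wild-type replicate 1, Bid only without wild-type replicate 2 and Hbb-bt without replicate 2 labelled Pou4f3KO. Mib1 and Col1a2 also did not pass with effective length taken into account, Lum, Tbx18 and Col1a2 in limma-voom, and Hbb-bt in DESeq2 and the fit of all libraries. Camera by limma gained lists as well: mesenchyme (adjusted p = 1.81e-05), glia (0.00706), immune (0.00910), endothelial (0.0127) and immediate early genes (0.0448) without replicate 1 labelled Pou4f3KO, synapse (0.0187) without replicate 2, and immune (0.0313), transcription factors and synapse (0.0428 each) without wild-type replicate 1. The immune list had enough tested genes for camera only with a library left out.

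ATOH1 occupied 36151 reproducible sites in wild-type hair cells, of which 26228, or 72.6%, were distal to genes. In E13 progenitors 44.6% of the sites (95% interval 44.1 to 45.2) were accessible, and in wild-type hair cells 69.7% (69.3 to 70.2), against 5.46% and 4.42% of the same sites at shifted positions. Among the distal sites 34.3% were accessible in progenitors and 64.3% in hair cells, and among the 9923 sites near gene ends 71.9% were accessible in progenitors. Of the 34101 accessible hair cell regions without ATOH1, 64.2% were accessible in progenitors. These regions were all accessible in wild type, so their shares here and below are not like for like with those of all ATOH1 sites. Of the 25215 ATOH1 sites accessible in wild type, 14691 were accessible in progenitors and 4563 overlapped POU4F3. POU4F3 overlapped 13.6% of ATOH1 sites (13.2 to 13.9; 0.789% at shifted positions) and 5.02% of the accessible regions without ATOH1. Its share of ATOH1 sites was 3.94% with peaks of −log10 q of at least 5 and 8.69% with the 20000 strongest peaks. The POU4F3 lists agreed poorly, with 14.3% of replicate 1 and 6.96% of replicate 2 found in the other list. The split into bound and unbound sites is uncertain to that extent. H3K4me1, a mark of enhancers, covered 75.7% of ATOH1 sites, H3K27ac, a mark of active elements, 40.4%, H3K4me3, a promoter mark, 32.1%, and the repressive mark H3K27me3 6.12%. The accessible regions without ATOH1 carried H3K4me1 at 53.1%, H3K27ac at 19.8%, H3K4me3 at 22.9% and H3K27me3 at 14.5%. These shares rested on requiring both replicates. The progenitor share was 24.3% or 12.1% and the hair cell share 33.0% or 15.7% when ATOH1 replicate 1 or 2 was left out, and the POU4F3 share was 39.5% without POU4F3 replicate 2 and 2.86% without ATOH1 replicate 2. H3K27me3 covered 10.7% or 11.3% of sites without its replicate 1 or 2, and H3K4me3 54.5% without its replicate 2.

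**Figure D3:**
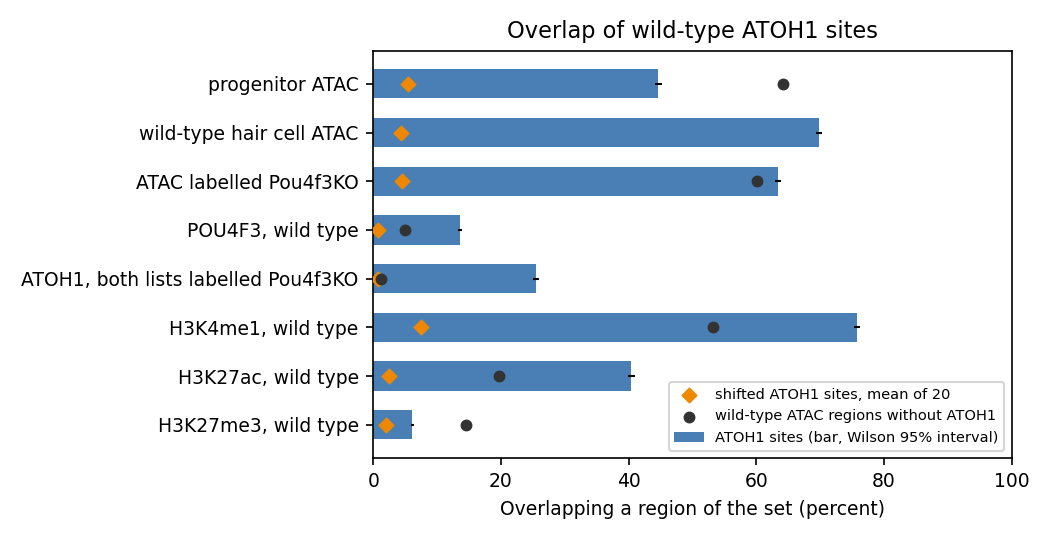
Percent of the 36151 wild-type ATOH1 sites (bars with Wilson 95% intervals), of the same sites at shifted positions (diamonds) and of accessible wild-type regions without ATOH1 (dots) that overlapped reproducible regions of each assay. Accessible sites made up 44.6% in progenitors and 69.7% in wild-type hair cells. The dots cover only regions accessible in wild type, while the bars cover all ATOH1 sites.

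ATOH1 sites that had opened since the progenitor stage were accessible less often in the lists labelled Pou4f3KO than sites already open in progenitors, and less often where POU4F3 was bound than where it was not. The Pou4f3 RNA level does not check that label. Of the 10524 ATOH1 sites closed in progenitors and open in wild-type hair cells, 58.1% (57.2 to 59.1) were accessible in the ATAC lists labelled Pou4f3KO, while of the 14691 sites open in both progenitors and wild type 95.2% (94.9 to 95.5) were. Among sites opened since the progenitor stage, 46.4% (44.3 to 48.4) of the 2265 POU4F3-bound sites and 61.4% (60.3 to 62.4) of the 8259 others were accessible. H3K4me1 at the bound sites covered 96.6% in wild type and 47.5% in the lists labelled Pou4f3KO, and at the others 91.4% and 60.4%. Over all wild-type accessible ATOH1 sites, accessibility was lost at 29.0% of the bound and 18.3% of the unbound, an odds ratio of 1.82 (1.69 to 1.95), or 3.28 (3.02 to 3.58) over strata of ATAC peak score. Among sites already open in progenitors the loss was 4.66% and 4.82%, an odds ratio of 0.965 (0.782 to 1.19), and 1.61 over the strata. Loss of accessibility was far more frequent at sites closed than at sites open in progenitors, 41.9% against 4.79%, an odds ratio of 14.3, or 8.26 over the strata. Without POU4F3 replicate 1 the odds ratio of accessibility loss was 1.22. With a peak in either list of each ATAC and POU4F3 pair counted it was 1.43. The wild-type ATAC lists had scores capped at 1000 and missed 143 and 140 peak numbers while those labelled Pou4f3KO showed neither, so this difference in processing ran with the label in every accessibility loss given here.

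Across all ATOH1 sites 63.3% (62.8 to 63.8) were accessible in the lists labelled Pou4f3KO against 69.7% in wild type. That order turned to 61.2% against 56.4% with peaks of −log10 q of at least 5, and to 33.6% against 31.0% with the 20000 strongest peaks of every list. H3K4me1 covered 59.2% of sites in the lists labelled Pou4f3KO against 75.7%. H3K27ac covered 26.6% against 40.4%, but 54.8% with replicate 1 labelled Pou4f3KO alone, while wild-type single lists gave 52.6% and 57.6%, so no difference in H3K27ac was detectable over all sites. At POU4F3-bound sites opened since the progenitor stage H3K27ac covered 60.8% (58.8 to 62.8) in both wild-type lists but 41.7% (39.7 to 43.7) in replicate 1 labelled Pou4f3KO alone, and at the unbound ones 39.6% and 48.8%. A single list gives higher shares than a pair of lists, and single wild-type lists are not given for these sites. The values at unbound sites therefore do not show a rise. H3K27ac replicate 2 labelled Pou4f3KO held 221 peaks with a −log10 q of at least 5 and came from a library made without the molecular tags of the others.

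ATOH1 itself had no peak in either list labelled Pou4f3KO at 45.0% of its wild-type sites (44.5 to 45.5), against 90.2% at shifted positions, and a peak in both lists at 25.4%. Those lists held 9369 and 5789 ATOH1 peaks with a −log10 q of at least 5, against 23237 and 36302 in wild type. A weaker assay could thus give part of this loss, which was not tested. The sites without a peak were 58.1% of those closed in progenitors and 28.7% of those open there, an odds ratio of 3.45 (3.30 to 3.61), or 3.25 over strata of ATOH1 peak score. With only wild-type ATOH1 replicate 2 or 1 as the reference, the lost share was 74.8% or 84.8% and the odds ratio 5.81 or 8.13. It was 62.5% and 55.2% without ATOH1 replicates 1 and 2 labelled Pou4f3KO, replicate 2 being the sample with conflicting stage labels. Where chromatin accessibility had been lost, 69.3% of sites had no ATOH1 peak, and where it was kept 26.4%, an odds ratio of 6.27. POU4F3-bound sites lost ATOH1 in 41.5% of cases and unbound sites in 45.5%, an odds ratio of 0.850 (0.800 to 0.904), or 0.325 without wild-type ATOH1 replicate 1 and 0.199 without replicate 2. Bound sites had stronger ATOH1 peaks, and over strata of peak score the odds ratio was 1.71 (1.60 to 1.84). Within the strata, from weakest to strongest, it was 0.909 (0.706 to 1.17), 1.31, 1.82, 1.73 and 2.39 (2.08 to 2.75), and in the strongest stratum 21.4% of bound and 10.2% of unbound sites had no peak. Among sites that had opened since the progenitor stage, 57.4% of bound and 43.9% of unbound sites had lost ATOH1. Among all sites closed in progenitors the shares were 59.3% and 58.0%, an odds ratio of 1.06 (0.972 to 1.15), or 2.24 over strata of peak score. Among sites open in progenitors they were 22.4% and 29.8%, an odds ratio of 0.681 (0.614 to 0.755), or 1.20 over the strata.

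**Figure D4:**
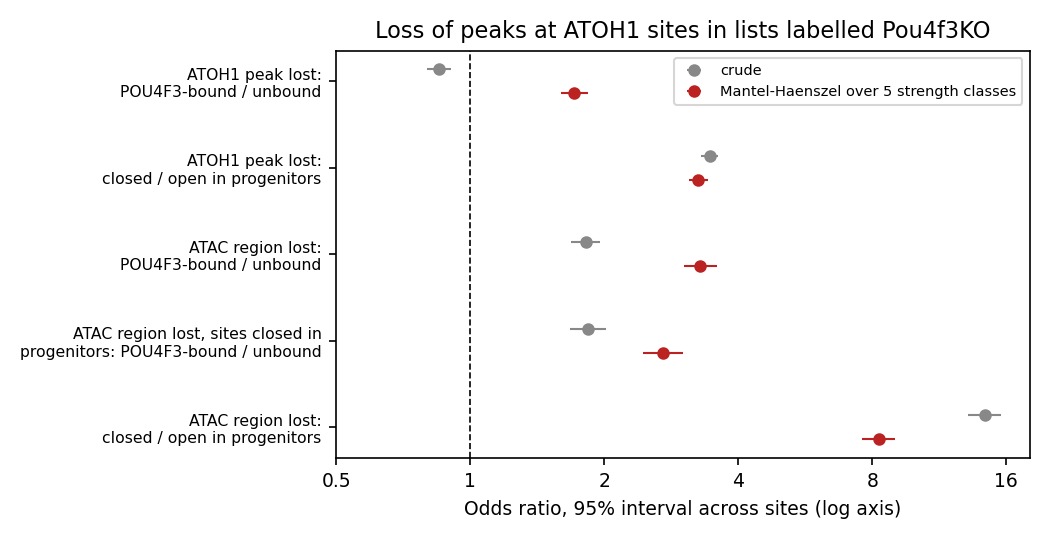
Odds ratios across sites (points) with 95% intervals (lines), without strata in grey and over strata of peak score in red, on a log axis, of losing the ATOH1 peak or chromatin accessibility in the lists labelled Pou4f3KO. For ATOH1 loss at POU4F3-bound against unbound sites the ratio was 0.850 without strata and 1.71 over strata of peak score.

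The strongest ATOH1 site linked to each of 11 hair cell genes stayed accessible in the lists labelled Pou4f3KO. Each also kept an ATOH1 peak in those lists, though at Lhx3 and Barhl1 not in both. Of all 71 ATOH1 sites linked to these genes 30, or 42.3%, had no peak in either list, near the 45.0% over all ATOH1 sites. Picking the strongest sites favours keeping, since in the strongest stratum only 21.4% of bound and 10.2% of unbound sites had no peak. On mm10, the site linked to Atoh1 lay on chromosome 6 from 64822918 to 64823922, its summit 92337 bp outside the gene, closed in progenitors and bound by POU4F3. The site linked to Pou4f3 lay on chromosome 18 from 42382196 to 42383307, its summit 12064 bp outside the gene, also closed in progenitors and POU4F3-bound. Further sites closed in progenitors lay inside Cdh23, which encodes the tip-link cadherin 23, on chromosome 10 from 60513237 to 60514239, inside Pcdh15, which encodes its partner protocadherin 15, on chromosome 10 from 74387632 to 74388558 with POU4F3, across an end of Barhl1, with the summit 229 bp outside it, on chromosome 2 from 28917671 to 28918696, and with the summit 11121 bp from Rasd2 on chromosome 8 from 75202588 to 75203469 with POU4F3. Sites already open in progenitors lay inside Gfi1 on chromosome 5 from 107723613 to 107724642, with the summit 16142 bp from Lhx3 on chromosome 2 from 26183663 to 26184298, inside Myo7a, an unconventional myosin gene, on chromosome 7 from 98111092 to 98111932, inside the actin-bundling gene Espn on chromosome 4 from 152131509 to 152132305 with POU4F3, and across an end of Tmc1, a transduction channel gene, with the summit 289 bp outside it, on chromosome 19 from 21037020 to 21037787 with POU4F3. The peak of the lists labelled Pou4f3KO was missed at the Atoh1 and Lhx3 sites when 50% of the site had to be covered, at Lhx3 without replicate 1, and at Barhl1 with a −log10 q of at least 5.

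The 5 strongest sites with POU4F3 that lost ATOH1 were closed in progenitors, open and marked by H3K4me1 in wild type, and closed in the lists labelled Pou4f3KO. They lay on chromosome 13 from 100962767 to 100963548, chromosome 18 from 30766468 to 30767266 and chromosome 12 from 45527459 to 45528242, with no protein-coding gene within 100 kb, on chromosome 18 from 54054305 to 54054986, with the summit 98936 bp from the kinase gene Csnk1g3, and inside the vesicle transport gene Vti1a on chromosome 19 from 55394311 to 55395048. H3K4me1 was found in the lists labelled Pou4f3KO only at the site on chromosome 18 from 30766468 among these 5.

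Genes linked to distal POU4F3-bound sites that lost ATOH1 were lower more often than other genes in the RNA libraries labelled Pou4f3KO, in which Pou4f3 itself was not lower. Of 930 such genes 219, or 23.5%, fell and 129, or 13.9%, rose. The odds ratio of falling was 1.36 against all other tested genes (1.16 to 1.59, two-sided Fisher's exact p = 0.000192), 1.57 against the other protein-coding genes, the only ones a site could be linked to (1.34 to 1.85, Fisher's exact p = 7.22e-08), 1.47 against 3995 genes near sites that kept ATOH1 (1.23 to 1.75, Fisher's exact p = 1.92e-05) and 1.12 against 832 genes near POU4F3-bound sites that kept it (0.886 to 1.41, Fisher's exact p = 0.362). Limma's camera on the set was not past the threshold (down, p = 0.172 with the preset and 0.698 with an estimated correlation), but it passed without replicate 2 labelled Pou4f3KO (down, p = 0.0156) and turned up without replicate 1 (p = 0.597). Hair bundle genes lay near such sites more often than other protein-coding genes, 14 of 49 (odds ratio 5.11, 2.53 to 9.79, adjusted Fisher's exact p = 9.93e-05), against 7.34% of the 12673 tested protein-coding genes, as did 9 of 34 transcription factors (4.58, adjusted exact p = 0.00272) and 21 of 121 deafness genes (2.69, adjusted exact p = 0.00190). The 10 deafness genes that were near such a site and fell included Adgrv1, Cacna1d, Cdh23, Chd7, Espn, Eya4, Myo3a, Myo6 and Whrn, and the 1 that rose was Pls1, which encodes the bundle protein plastin 1; these were named after their values were seen. Synapse genes (7 of 38, odds ratio 2.87, adjusted exact p = 0.0667), progenitor genes (5 of 44, adjusted exact p = 0.429) and cell cycle genes (1 of 50, adjusted exact p = 0.429) did not pass. These list tests did not match genes for length or for their number of ATOH1 sites. Long genes and genes with many ATOH1 sites can be linked to such sites more often, so the shares do not show a tie to POU4F3 dependence. Without replicate 2 labelled Pou4f3KO the odds ratio of falling was 2.32, and it no longer passed without wild-type replicate 1 (1.35, Fisher's exact p = 0.0579) or wild-type replicate 2 (1.25, Fisher's exact p = 0.178).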

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

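The count below was chosen after the data were seen. The 24 peak lists held 1189 peaks on sequences outside chromosomes 1 to 19, X and Y, which entered no comparison, and no control sample gives a background for them. They were most numerous in wild-type ATOH1 replicate 1, at 193 peaks, and took their highest share in H3K27ac replicate 2 labelled Pou4f3KO, at 0.129% of its peaks, 5 of them mitochondrial. Both ATAC lists of progenitors and of wild-type hair cells, both H3K4me3 lists and both ATOH1 lists labelled Pou4f3KO held 0.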

How the results depend on the processing

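Settings added after the data were seen were a background of protein-coding genes for linked genes, offsets for effective length, protein-coding genes over 1 kb, a peak in either list, stricter peaks for region counts and histone marks, and histone marks without a replicate. Among the main results 126 alternatives kept direction and side of the threshold or lay within the spread, 100 moved, 3 reversed and 2 became weaker; among single genes, sites and lists 2149 kept, 106 weakened, 25 strengthened, 9 reversed and 4 moved. The motif alternatives fixed in advance were not run without a genome sequence. The effect of depth was not tested; the RNA libraries labelled Pou4f3KO were the shallowest, at 3966727 and 3581930 counts. The cause of the changes below was not tested unless given.

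With an estimated correlation, 0 of the 5 lists called between the hair cell labels and 0 of the 10 called between hair cells and progenitors passed limma's camera, a test of little power with 4 libraries. With the replicate number as a block, calls were 2014 higher and 2527 lower by label and 4982 and 4438 between stages, the camera calls stayed at 5 and 10, and the odds ratio for linked genes was 1.66. Under this block Tbx18, Col1a2 and Hbb-bt lost their calls. Samples with the same number deviated together at a correlation of 0.063 by label and 0.0307 between stages, so the numbers are not shown to pair them.

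With peaks of −log10 q of at least 5, ATOH1 sites were accessible at 41.9% in progenitors, 56.4% in wild type and 61.2% in the lists labelled Pou4f3KO, 62.0% were lost, and the odds ratio of loss at POU4F3-bound sites reversed to 1.27. With the 20000 strongest peaks the shares were 23.2%, 31.0% and 33.6% and the ratio reversed to 1.78, as it did over score strata, to 1.71, where peak strength is held constant. The share bound by POU4F3 was 3.94% with the stricter q and 8.69% with the 20000 strongest peaks. With 50% of the site covered the shares were 36.7%, 60.3% and 53.4% with 66.6% lost, and in a 200 bp window 41.6%, 67.3% and 60.7% with 52.0% lost, both smaller targets by construction. Distal sites gave 34.3%, 64.3% and 56.9%. A peak in either list gave 52.4%, 82.3% and 74.5%, with POU4F3 at 46.8%.

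Reproducible regions with −log10 q of at least 5 fell to 66627 for progenitor ATAC, 31967 for wild-type ATAC, 16377 for wild-type ATOH1, 1205 for POU4F3, 71839 for H3K4me1, 5011 for H3K27ac, 16336 for H3K4me3 and 3340 for H3K27me3, and in the lists labelled Pou4f3KO to 48941 for ATAC, 3164 for ATOH1, 47935 for H3K4me1 and 214 for H3K27ac. With the 20000 strongest peaks they were, in the same order, 17384, 14068, 12711, 2777, 11378, 7131, 12745 and 7436, and 15925, 5427, 9130 and 8463. Fewer peaks entered by construction. With the stricter peaks H3K4me1 covered 77.8% of ATOH1 sites in wild type and 47.7% in the lists labelled Pou4f3KO, H3K27ac 13.9% and 0.782%, H3K4me3 21.1% and H3K27me3 1.12%.

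Leaving out each library in turn, with the lone sample assumed to vary like the other group, genes by label ranged from 213 to 4035 higher and from 563 to 4702 lower, 810 to 8737 in all, and lists called from 5 to 9 among those tested with all libraries, or 10 with the immune list, tested only with a library left out. Few calls were left without a wild-type library and many without a library labelled Pou4f3KO. Adjusted p-values of lists that turned direction in limma's camera ranged from 0.179 to 0.750 for deafness, 0.226 to 0.937 for Notch and 0.0127 to 0.935 for endothelial genes by label, and from 0.545 to 0.863 for mesenchyme between stages. Log2 fold changes that turned ranged from −0.19 to 0.62 for Atoh1, −2.52 to 4.15 for Kdr and −2.46 to 3.51 for Cdh5. Between stages the calls ranged from 3392 to 5922 higher and from 2848 to 5371 lower, 6240 to 11293 in all. The odds ratio for linked genes ranged from 1.25 to 2.32, past the threshold only with both wild-type libraries.

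With single lists, accessible shares ranged from 12.1% to 48.8% in progenitors, 15.7% to 77.3% in wild type and 15.0% to 70.3% in the lists labelled Pou4f3KO, POU4F3 from 2.86% to 39.5% and lost sites from 55.2% to 84.8%. H3K4me1 ranged from 79.1% to 79.7% in wild type and from 64.2% to 67.5% in the lists labelled Pou4f3KO, H3K27ac from 52.6% to 57.6% and from 27.7% to 54.8%, H3K4me3 from 39.8% to 54.5% and H3K27me3 from 10.7% to 11.3%.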

Other observations

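Of the tests below, those of exchanged RNA libraries, of peak strength and of gene ends were chosen after the result was seen, as were the genes named as lower protein-coding leaders.

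Among the classes of accessible region, those accessible in wild-type hair cells alone held POU4F3 most often, and those closed in progenitors and accessible in hair cells of both labels held ATOH1 most often. Regions accessible in wild-type hair cells alone numbered 18365, of which 17.5% overlapped POU4F3 and 27.5% ATOH1, and 31.1% of them held a peak in at least 1 ATAC list labelled Pou4f3KO. Regions shared by hair cells of both labels and closed in progenitors numbered 11694, with POU4F3 at 12.0% and ATOH1 at 53.2%. The 40521 regions accessible in all 3 kinds of cell held POU4F3 at 8.20% and ATOH1 at 34.7%, and the 37610 accessible in progenitors alone held them at 0.747% and 1.77%. Accessible regions of the lists labelled Pou4f3KO alone, 18888 in number, held POU4F3 at 1.21% and ATOH1 at 11.0%. The 17399 regions shared by progenitors and the lists labelled Pou4f3KO held them at 1.46% and 5.75%, and the 5937 shared by progenitors and wild type at 4.78% and 11.6%.

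POU4F3 occupied 15212 reproducible sites, of which 32.1% overlapped an ATOH1 site. They were accessible at 26.0% in progenitors, 50.8% in wild-type hair cells and 33.0% in the ATAC lists labelled Pou4f3KO, and H3K4me1 covered 54.7%. Among ATOH1 sites, those with POU4F3 were accessible in wild type at 93.1% and those without at 66.1%, and H3K4me1 covered 91.0% and 73.4%. Protein-coding genes lowest in the RNA libraries labelled Pou4f3KO included the apolipoprotein genes Apob, at least 34.89-fold, and Apoa4 at −7.84 (SE 0.96), the spectrin gene Sptbn5, at least 41.7-fold, and the kinase gene Cdk15, at least 38.6-fold. Fam205a3 and Fam205a2, at least 50.5-fold each, had the same values and share reads as near-identical copies.

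Pou4f3 mRNA was not lower in the RNA libraries labelled Pou4f3KO, and its log2 fold change was 0.98 (SE 0.30) with effective length taken into account. Effective length therefore does not account for the level. Fragments were longer in these libraries, which shortens the effective length, so the offset could hardly have lowered the fold. Further effects of fragment length were not tested. An exchange of the RNA libraries between the hair cell labels would turn the RNA directions between those labels, and the labels' protocol words the wild-type hair cell tissue as wild type and mutant at once. It would not by itself explain a Pou4f3 transcript in mutant cells. The libraries labelled wild type also held Pou4f3, at 595.6 and 544.6 CPM, against 0.469 and 1.64 CPM in progenitors. If genes near POU4F3-dependent sites fall when POU4F3 is lost, which is assumed here, an exchange would put them among the lower genes less often than others, yet their odds ratio was 1.36, and above 1 in every alternative (1.25 to 2.32), at 1.35 and 1.25 without wild-type replicate 1 and 2 (Fisher's exact p = 0.0579 and 0.178). This does not exclude an exchange, because Fisher's test takes genes as independent, while limma's camera on the set gave p = 0.172, with the direction up without replicate 1 labelled Pou4f3KO (p = 0.597) and down without replicate 2 (p = 0.0156). An allele that leaves a transcript also stays open, untested, because the labels do not describe the allele.

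Cell cycle and progenitor genes were higher and hair bundle genes lower in the RNA libraries labelled Pou4f3KO by limma's camera, though for none of these lists with an estimated correlation (adjusted p = 0.592 each). Admixed E13-type progenitors would have to make up 37.3% of the RNA by cell cycle genes, 41.6% by progenitor genes and 43.0% by hair bundle genes. Yet 36 genes abundant in progenitors and scarce in wild-type hair cells reached a median of 3.46% of their progenitor level (bootstrap 95% interval over genes 1.79 to 5.26). This argues against such cells as the main source but does not exclude them. The 36 genes were picked between libraries of different kits, and the hair cell kit may read some of them poorly. Effective length does not account for the higher cell cycle genes, since their median log2 fold change was 1.28 with it taken into account and 1.27 without. Further effects of fragment length were not tested. Other cells, such as E17 supporting cells or mesenchyme, which the Atoh1-GFP+ sort should remove, the scarcity of small RNA in these libraries, and a response to the mutation could each contribute and stay open, untested. Mesenchyme markers summed to 423 and 2284 CPM in replicates 1 and 2 against 328 and 369 CPM in wild type, while cell cycle genes took 1029 and 1397 CPM against 629 and 604 CPM.

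ATOH1 peaks were lost less often at POU4F3-bound than at unbound sites without strata, at an odds ratio of 0.850, or 0.325 and 0.199 without wild-type ATOH1 replicate 1 and 2. A likely reason is peak strength, since bound sites made up 4.69% of the weakest and 27.3% of the strongest stratum, and over strata of peak score the odds ratio was 1.71. Mixing of sites near gene ends with distal ones does not account for it, since among distal sites alone the odds ratio was 0.900 (0.840 to 0.965). Loss of ATOH1 at POU4F3-bound sites beyond what peak strength gives stays a hypothesis, because sites are not independent and the lists labelled Pou4f3KO came from few samples with differing processing.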
